A study of Homo sapiens with 2 samples.

How the data were processed

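4C-seq libraries of 2 independent experiments on U2OS cells carrying DRGFP, TRE-I-SceI and Tet-On transgenes were analysed. Per the labels' protocols, cells were fixed in 2% formaldehyde and lysed, the chromatin was cut with 400 U of HindIII and ligated, the DNA was cut again with Csp6I and circularised, and contacts were amplified by inverse PCR of 30 cycles from primers in the transgene, followed by 8 cycles after adapter ligation and sequencing on an Illumina instrument. PCR of this kind favours short fragments and multiplies single ligation events, and there are no molecular identifiers, so a high value can stem from few molecules.

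The deposited table gives, per the file headers, 1 signal column for each experiment over windows of 50 kb, called probes, with a gene name, its orientation and its distance. The build was hg18, per the submitters' processing notes; the aligner, the read filters, the counting tool, the gene annotation and the handling of the vantage-point fragment are not given in the sources used here. The signal values that the authors deposited proved to be reads per 1000000 reads of the library (RPM): all were whole multiples of about 1.06 in replicate 1 and of 2.20 in replicate 2, and 100% of them gave whole reads within a tolerance of 0.1 read. From these steps the libraries held 944456 and 454091 reads, and the probes sum to 0.282% and 0.0852% more, as reads counted in 2 neighbouring probes would give. The final 2 rows of the table, a column total and a mean, were left out, as was the single mitochondrial probe, at 0 in both, which leaves 61607 probes. The design, fixed before the data were examined, allowed for several units; the rank and log2 tests it gives for a linear unit were used, and a negative binomial test of the recovered reads was run as an added alternative.

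Of the probes, 36139 overlap a gene, 260 lie within 998 bp of one and 25208 have no gene; 47 carried a spreadsheet date in place of a gene name and were not named. Of 18644 distinct names, 10829 matched a current symbol and 2025 a single synonym in a RefSeq gene table of GRCh38.p14, used for names alone. Clone-based names and microRNA names, 5734 in all, were kept in the tests, and clone-based names are not printed. A probe has 1 gene name, so genes that share a window with another can be missing. No hg18 sequence or restriction map was used, so the number of HindIII fragments per probe, which limits its detection, was not corrected for.

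Each replicate was analysed alone and the 2 were set side by side, with the mean ± SD. Agreement was measured on log2(RPM + 1). Windows of 500 kb with at least 10 probes were ranked by mean signal, and the centre of the top window served as vantage point for distances, in bins that widen by a factor of 2 from 10 kb. Ranks run from 0 to 100 within a replicate. Contact windows on other chromosomes were called by the mean rank of their probes against 10000 random draws, one-sided, with Benjamini-Hochberg adjustment at 0.05 in each replicate, and had to pass in both; on chromosome 12, beyond 2 Mb, ranks were taken within distance bins. Their overlap, the correlations, gene density in 1 Mb windows and gene classes were tested by 10000 circular shifts along the genome, which keep neighbouring probes together; the smallest p is 1e-04. Probe density is uniform, so the partial correlation planned for it could not be computed. Medians of probe classes tied at the rank of a probe without reads, so differences of means were tested.

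The 17 gene lists, fixed before the data were examined, were double-strand break repair, core histones, olfactory receptors, zinc finger genes, protocadherins, keratins, HOX clusters, ribosomal proteins, immunoglobulin and T-cell surface genes, liver, neuronal, bone and mesenchymal genes, genes gained in osteosarcoma, common fragile site genes, p53 targets, cell cycle and replication genes, and housekeeping genes. Named by rule were the 10 gene names with the highest probes within 5 Mb of the vantage point, at most 2 genes in each of the top 10 windows on other chromosomes and the top 5 on chromosome 12, and the 2 highest and the lowest member of each list, by the lower of the 2 replicates; ties went alphabetically, and members tied without reads are mostly left out.

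Alternatives covered the scale, filters, window size, thresholds, background and leaving out each replicate. Stretches of raised detection were placed by the binomial likelihood of 1 segment per chromosome, and the trend of detection within a segment was tested in 1 Mb blocks by 100000 permutations, in the replicate that had not placed it. The procedures were tested on simulated data. Among 5882 windows, 62% of windows with 8-fold raised detection and 94% with 10-fold were called, 0% with 4-fold or 2-fold, and 0 of 5682 unraised windows. In that simulation the probes were shuffled, which removes clustering, and 50 windows at each fold were raised at once. Among 17757 genes, 6 of 100 random lists of 25 genes had a p under 0.05 by the mean rank over genes, and all 50 lists with 4-fold raised detection did. Fewer draws were used there than in the analysis, and the planned list test by the median was not simulated. Of 100 unrelated replicate pairs over 58961 probes, 4 had a p under 0.05, and planted edges in 3000 probes were found with a median error of 3 probes. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.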

Results

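Contacts of a single genomic site were mapped by 4C-seq in U2OS, a human osteosarcoma cell line. In 4C, crosslinked chromatin is cut and ligated, and inverse PCR from a chosen fragment (the vantage point) recovers the sequences ligated to it, so that read number reflects nearness in the nucleus. The vantage point was a fragment beside the I-SceI cutting site of DRGFP, an integrated reporter for repair of double-strand breaks by homologous recombination. The study addressed which parts of the genome lie near this break site. Both libraries form 1 group of 2 independent experiments, with no control group and no treatment recorded, so the comparisons are between the experiments and between regions within each. The values cover 61607 probes of 50 kb that tile the genome (hg18), as reads per 1000000 reads of the library (RPM). Replicate 1 held 944456 reads on 4963 probes (8.06%) and replicate 2 held 454091 reads on 5316 probes (8.63%). A single read was the whole signal at 35.7% of the detected probes of replicate 1 and at 27.7% of those of replicate 2. With 2 experiments, SDs are imprecise, and intervals on shares of reads cover counting error only, since PCR copies are not independent molecules.

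Chromosome 12 held 68.0% ± 2.21 of the reads (SD, n = 2) while carrying 4.29% of the probes. Chromosome 6 followed with 8.37% ± 1.80 and chromosome 17 with 2.67% ± 0.158, in the same order in both replicates. Reads reached 24.3% ± 2.09 of the probes of chromosome 6 and 19.9% ± 0.828 of those of chromosome 12, and on chromosome 17 they reached 15.9% in replicate 1 and 18.04% in replicate 2. On the remaining autosomes and the X chromosome, between 3.83% and 8.09% of a chromosome's probes had reads in replicate 1, and between 3.73% and 8.92% in replicate 2. The 95% Clopper-Pearson interval of chromosome 12 was 66.3% to 66.5% of reads in replicate 1 and 69.4% to 69.7% in replicate 2, so the replicates differed by more than counting error. By share of detected probes instead of reads, chromosome 6 ranked above chromosome 12 in both replicates.

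**Figure D1:**
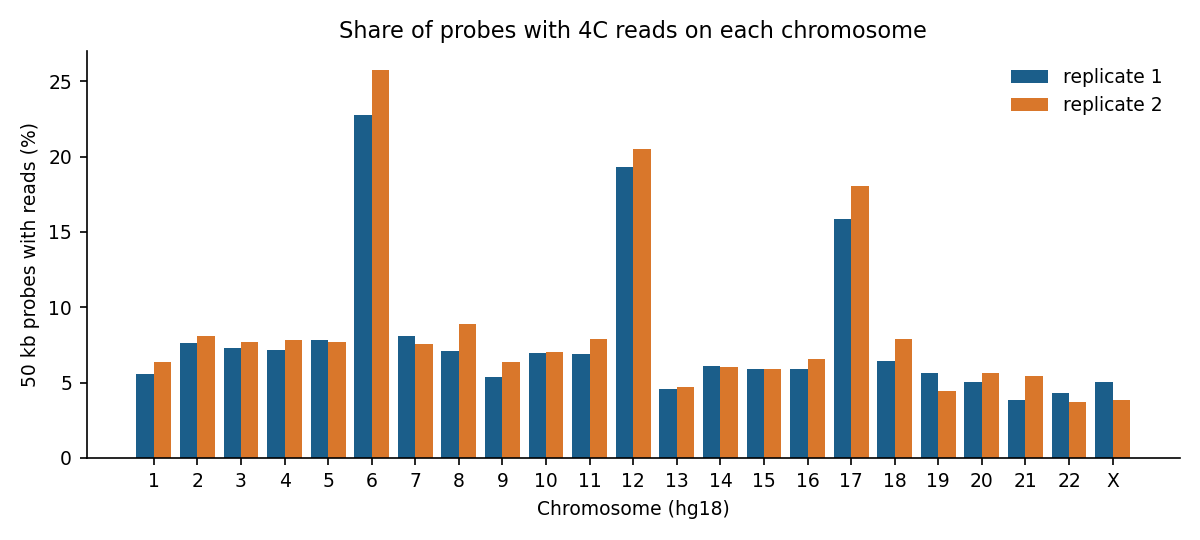
Share of 50 kb probes with at least 1 read (y axis, percent) on each autosome and the X chromosome (x axis), with 1 bar per replicate. Chromosomes 6, 12 and 17 stand above the others in both replicates, which lie between 3.73% and 8.92%; chromosome Y is not drawn.

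The strongest signal lay at GRIN2B, the gene of a subunit of NMDA-type glutamate receptors, on chromosome 12. The 500 kb window from 13500001 to 14000000 ranked first in both replicates, with 31345 and 31974 RPM per probe, and held 31.6% ± 0.488 of all reads (n = 2). Within 1 Mb of its centre at 13.75 Mb lay 54.1% ± 2.29 of all reads, and within 5 Mb 64.2% ± 2.30. The single highest probe, from 13800001 to 13850000 and overlapping GRIN2B, reached 104053 ± 2416 RPM. This window is the region of strongest signal and not a sequenced insertion site, and its centre moved to 13.9 Mb with 200 kb windows and to 13.5 Mb with 1 Mb windows.

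Of the 10 gene names with the highest probes within 5 Mb of that centre, 6 were gene symbols and the others were clone-based names. After GRIN2B came EMP1, which encodes an epithelial membrane protein, with 20515 ± 1282 RPM at its highest probe (13250001 to 13300000). The non-coding C12orf36, now LINC01559, had 13669 ± 1853 (13400001 to 13450000). ATF7IP, a nuclear partner of the histone methyltransferase SETDB1, had 12202 ± 289 (14450001 to 14500000). GPRC5A, an orphan receptor gene, had 6864 ± 360 (12950001 to 13000000), and KIAA1467, now FAM234B, had 3498 ± 148 (13050001 to 13100000). Each of these probes overlaps its gene in the deposited annotation, which does not say whether exon or intron. The SD between replicates was below the difference from EMP1 to GRIN2B and from GPRC5A to KIAA1467, with no test run on these values.

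Signal on chromosome 12 fell with distance from 13.75 Mb, with a log-log slope of -1.31 ± 0.0124 (n = 2). From 640 kb to 1280 kb the mean was 3145 and 3409 RPM per probe in replicates 1 and 2, and all 26 probes had reads. From 5120 kb to 10240 kb it was 107 and 101, with reads at 56.3% and 63.1% of probes. From 40960 kb to 81920 kb it was 5.83 and 4.34, close to the 4.02 and 3.95 of chromosomes other than 6, 12, 17 and Y. The slope was -1.08 ± 0.0174 when distances were limited to 8 Mb, -1.01 ± 0.0332 towards the chromosome start and -1.37 ± 0.0110 towards its end. No test between replicates was made, as each gives a single slope.

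**Figure D2:**
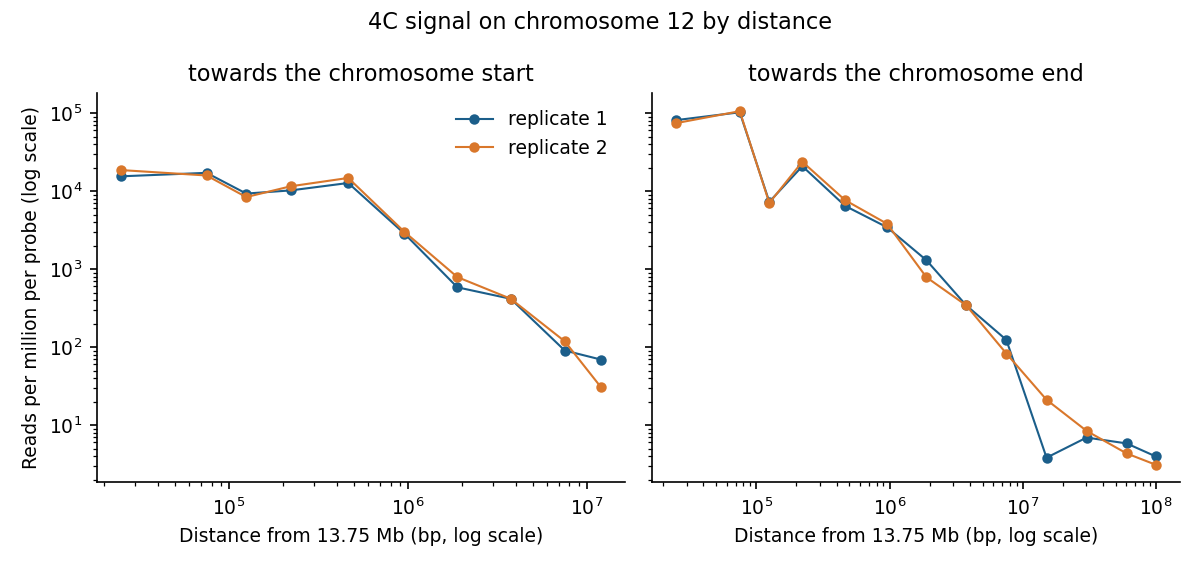
Mean RPM per probe (y axis, log scale) by distance from 13.75 Mb on chromosome 12 (x axis in bp, log scale), towards the start (left) and the end (right) of the chromosome, with 1 line per replicate. Both lines fall from above 10000 to below 100 on each side.

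The fall with distance was not gradual everywhere. On chromosome 12 the probes up to 21.85 Mb had reads at 81.5% ± 1.62 of positions, and those beyond at 7.72% ± 0.672. The probe that overlaps KCNJ8, a potassium channel gene (21800001 to 21850000), had 89 and 27 reads, and the next 7 probes, from ABCC9 on, had 0 in both replicates. On chromosome 6, 6.23% ± 1.23 of probes before 34.5 Mb and 28.8% ± 2.93 of those after it had reads. Detection was highest in a segment that ended at 57.6 Mb in replicate 1 and 57.95 Mb in replicate 2. Reads reached 60.8% and 66.7% of its probes, against 16.8% and 19.3% on the rest of the chromosome, before and after it. The rise went on beyond the segment, with reads at 18.4% ± 2.30 of probes in the last 20 Mb. The segment's end lies near the 1 Mb windows starting at 59, 60 and 61 Mb, which had no reads in either replicate. On chromosome 17 the stretch from 54.1 Mb to 76.35 Mb had reads at 44.7% ± 5.08 of probes, against 5.82% ± 0.261 before it. The end of that stretch is uncertain, at 71.75 Mb from replicate 1 and 76.35 Mb from replicate 2. These boundaries were placed from the data by likelihood, after the profiles had been seen, and KCNJ8 and ABCC9 were chosen after their values were seen.

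**Figure D3:**
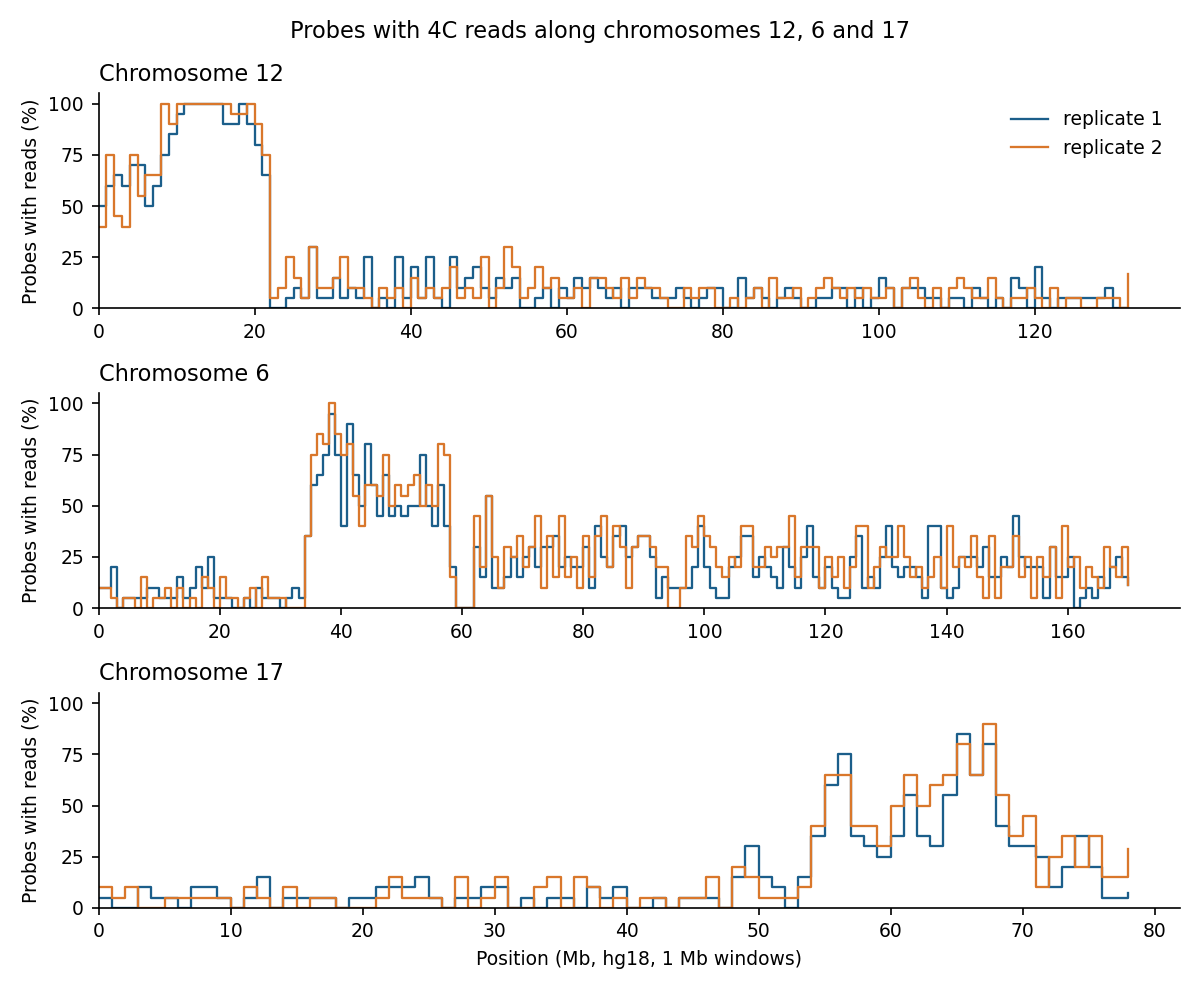
Share of 50 kb probes with reads (y axis, percent) in 1 Mb windows along chromosomes 12, 6 and 17 (x axis, Mb), with 1 line per replicate. Detection drops near 21.85 Mb on chromosome 12 and rises near 34.5 Mb on chromosome 6 and near 54.1 Mb on chromosome 17.

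The replicates shared the pattern on chromosome 12 more closely than elsewhere. Across probes, Pearson's r of log2(RPM + 1) was 0.774 on chromosome 12, 0.188 on the other chromosomes and 0.323 over all (Spearman's rho 0.646, 0.197 and 0.243). Each had a two-sided permutation p of 1e-04 by circular shifts along the genome, the smallest they can give, and an adjusted p of 1.12e-04 over 28 relations; probes are not independent replicates. Reads were found in both replicates at 1529 probes, 3.57 times the 428 that independent libraries would share. Where both had reads on other chromosomes, rho of their levels was -0.0863 (adjusted p = 0.0331 by permutation). Presence was thus shared there, while the ranks of the levels did not agree. Reads carried over between the libraries, taken up at the end, could lower this rho. Pearson's r of untransformed RPM over all probes of these chromosomes was 0.479. Among the 1529 shared probes, 69.1% differed between libraries beyond counting error, so the 2 are not a single library deposited again.

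Away from chromosome 12, 58 windows of 500 kb were called in both replicates, 41 on chromosome 6 between 34.5 Mb and 151.5 Mb and 17 on chromosome 17 between 54.5 Mb and 68.5 Mb. None of the 5384 windows on other chromosomes was called. The 58 windows held 17.9% and 15.3% of the reads off chromosome 12 in replicates 1 and 2 (6.03% and 4.66% of all reads), while chromosomes other than 6, 12, 17 and Y held 21.2% and 20.8% of all reads. The top windows held SOX9, a transcription factor gene of cartilage development, on chromosome 17 and NFYA, a subunit of the CCAAT-binding factor NF-Y, on chromosome 6. Replicate 1 alone called 77 windows and replicate 2 alone 114 of 5882 tested, and shifts of one along the genome gave 1.44 shared windows on average (one-sided permutation p = 1e-04, the smallest they can give).

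Genes in the 10 windows with the highest ranks were, on chromosome 6, ZFAND3, BTBD9, KIF6, DAAM2, DNAH8, MDGA1, UNC5CL, NFYA, GPR110 (now ADGRF1), TNFRSF21, USP49 and FRS3. On chromosome 17 they were SOX9, KCNJ2 and KCNJ16, the last 2 being inward-rectifier potassium channel genes. The first window, from 38000001 to 38500000 at ZFAND3 and BTBD9, had reads at all 10 of its probes in both replicates. ZFAND3 (38100001 to 38150000) had 147 ± 3.32 RPM and KIF6, a kinesin gene (39550001 to 39600000), 317 ± 46.9. GPR110 (47100001 to 47150000) had 457 ± 23.2, and DAAM2, a formin gene of Wnt signalling (39950001 to 40000000), 108 ± 6.79. Others differed widely between replicates: UNC5CL (41100001 to 41150000) had 2754 and 511 in replicates 1 and 2, NFYA (41150001 to 41200000) 1202 and 258, and SOX9 (67600001 to 67650000) 209 and 81.5. KCNJ2 (65650001 to 65700000) had 73.1 and 308, and USP49, a deubiquitinase gene (41950001 to 42000000), 304 and 1599.

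The number of windows moved with the setting: 24 were called with ranks taken within each chromosome, 38 by share of probes with reads, and 19, still all on chromosomes 6 and 17, when only probes with at least 10 reads counted. With chromosomes 6 and 17 left out of the test 0 were called, although 46 of 5384 had an unadjusted p under 0.05 in both replicates against 18.1 by shifts. With 10000 draws, a few raised windows among 5384 cannot reach an adjusted p under 0.05, so 0 called does not exclude contacts there. A negative binomial test of the recovered reads called 1 window, at HPRT1 on the X chromosome. In simulations, windows with 8-fold raised detection were called in 62% of cases and those with 4-fold in 0%, with no strength in between tried. There the probes were shuffled and 50 windows at each strength were raised at once, which eases the adjustment. The 62% therefore does not hold where only a few windows are raised.

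On chromosome 12 beyond 2 Mb from the centre, 2 of 255 windows stood above others at like distance in both replicates. The window from 19000001 to 19500000 holds PLEKHA5, a pleckstrin homology domain gene, and AEBP2, a cofactor of the Polycomb complex PRC2. All 10 of its probes had reads in both replicates. The window from 1000001 to 1500000 holds ERC1, a scaffold gene of vesicle docking, with reads at 7 and 9 of 10 probes. The highest PLEKHA5 probe (19250001 to 19300000) had 646 and 297 RPM, the AEBP2 probe (19450001 to 19500000) 13.8 and 405, and the ERC1 probe (1150001 to 1200000) 198 and 26.4. Shifts gave 0.0617 shared windows on average (one-sided permutation p = 0.00470). With 1 Mb windows 5 were called, with 200 kb windows 0, replicate 1 alone gave 6 and replicate 2 alone 3, so these rest on few windows. The distance bins pool both sides of the centre, while signal towards the chromosome end stops near 21.85 Mb. In the bin from 10240 kb to 20480 kb, which holds ERC1, 58.6% and 48.6% of probes towards the start had reads against 10.2% and 15.1% towards the end. With bins of each side alone, an alternative chosen after seeing the data, 1 window was called (one-sided permutation p = 0.0394): the PLEKHA5 window passed in both replicates, and the ERC1 window had an adjusted p of 0.815 in replicate 1 by the random draws. The bin from 5120 kb to 10240 kb, which holds the PLEKHA5 window, runs past 21.85 Mb towards the chromosome end. Probes beyond that edge count in both settings, so neither separates the PLEKHA5 window from the edge.

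Windows without a gene name had reads least often. Over 1 Mb windows of chromosomes other than 6, 12, 17 and Y, 1.94% of probes had reads where no gene was named, in each replicate. The share was 7.06% ± 0.254 with 1 to 3 names, 7.57% ± 0.212 with 7 to 9 and 6.29% ± 0.237 with 10 to 20. Over all 2935 windows off chromosome 12, Spearman's rho between gene names per window and mean rank was 0.112 and 0.106 in the 2 replicates. For their mean it was 0.124 (Pearson's r 0.0676, two-sided permutation p of rho = 1e-04, the smallest that shifts can give). Limited to the 2693 windows with a gene name, rho was -0.0430 (permutation p = 0.359), so the relation rested on windows without genes. Windows are not independent replicates, and assembly gaps, which hold neither reads nor gene names, were not separated from gene-free sequence.

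Probes that overlap a gene had reads more often than the rest, 8.53% against 6.83% of probes on the other chromosomes (adjusted p = 4.5e-04, two-sided permutation by shifts). Without chromosomes 6, 17 and Y the shares were 7.04% and 6.06% (adjusted p = 6.00e-04 by the same permutation). Assembly gaps were not separated from the probes without a gene, and only 1.94% of probes in 1 Mb windows without a gene name had reads. These 209 windows are numerous and low enough to make up nearly all of the difference seen without chromosomes 6, 17 and Y. No test was run on the probes outside them. Probes within 998 bp of a gene without overlap, 247 in number, had reads in 7.89% of cases against 7.82% for all others. The mean rank of overlapping probes lay 0.863 above that of others (50.4 against 49.5), in the same direction in both replicates.

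None of the 17 gene lists stood apart from shifted positions after adjustment, by the median or by the mean rank over genes (0 with adjusted p under 0.05). Of the 17757 genes on other chromosomes, 13.7% had reads in replicate 1 and 14.0% in replicate 2, and the median gene of most lists sat at the rank of a probe without reads, 46.1, where the median cannot move. The highest mean rank, 59.8 against 50.04 under shifts, was that of genes gained in osteosarcoma (two-sided permutation p = 0.00580, adjusted p = 0.0986). Of its 16 members 4 lay in called windows of chromosome 6: PIM1, a kinase gene, CCND3, which encodes cyclin D3, CDC5L, a spliceosome component, and RUNX2, the transcription factor gene of bone formation. PIM1 (37200001 to 37250000) had 248 and 132 RPM and CCND3 (42050001 to 42100000) 1093 and 4.40, while AURKB had none. The adjusted p of its mean was 0.0102 against random genes with as many probes per gene, the single setting that called a list, and otherwise ran from 0.0799 in replicate 1 alone to 0.940. That last value is for its 7 members off chromosomes 6 and 17, with a mean rank of 50.4.

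Among 39 genes of double-strand break repair, 12 had reads in replicate 1 and 6 in replicate 2, and their mean rank was 51.6 (adjusted p = 0.889 by permutation). BRIP1, a helicase gene (57200001 to 57250000 on chromosome 17), had 817 and 260 RPM, and RNF8, a ubiquitin ligase gene of the break response, also lay in a called window. BLM, a helicase gene, had 164 RPM in replicate 1 and 0 in replicate 2 at its highest probe. Over its 3 probes its mean rank in replicate 2 was 62.8, above the 46.0 of a probe without reads. Another BLM probe thus had reads in replicate 2. ATM, a kinase gene of the break response, had 0 in both replicates. Common fragile site genes, which are long, had reads at 20 and 18 of 24 members, with a mean rank of 49.7. DISC1 and PTPRN2 ranked highest of these, and ESRRG had no reads at its highest probe.

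The other lists had mean ranks from 47.5 for protocadherins to 52.4 for bone and mesenchymal genes, and their adjusted p values by permutation were 0.889 or above. RUNX2 led the bone list, with 122 and 15.4 RPM at its highest probe, and was its single member with reads in both replicates. Of 313 zinc finger genes, with a mean rank of 50.4, 43 and 30 had reads, ZNF451 first, and of 156 olfactory receptor genes, with 50.2, 12 and 17 did, OR9A2 first. Keratins had a mean rank of 51.9, ribosomal protein genes 52.0 and cell cycle and replication genes 52.1, and in these 3 lists 0 members had reads in both replicates, so none is named as the highest. Mean ranks were 50.6 for core histone genes, 50.1 for HOX genes, 51.3 for immunoglobulin and T-cell surface genes, 50.2 for liver genes, 49.2 for neuronal genes, 49.9 for p53 targets and 48.0 for housekeeping genes. PPM1D, a phosphatase gene induced by p53, had 4.24 and 13.2 RPM in a called window of chromosome 17, and CNTN4 led the neuronal genes.

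HPRT1, a purine salvage gene on the X chromosome, was the single housekeeping gene of 14 with reads. Its probe from 133400001 to 133450000 had 12127 and 10060 RPM (11093 ± 1462), ranking 13 and 17 among all probes of the genome. The probes on either side of it had no reads in either replicate.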

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

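Alternatives named here as added were chosen after seeing the data. By share of detected probes in place of reads, chromosomes 12, 6 and 17 held 10.2%, 16.1% and 5.19%, and without the 10 highest probes 49.8%, 13.1% and 4.18%; leaving out a replicate gave 66.4% to 69.5%, 7.09% to 9.64% and 2.56% to 2.78%. Agreement over all probes had rho 0.155 (permutation p = 0.0879) over probes with reads in both, and with at least 10 reads in either r was -0.386 over all, 0.336 on chromosome 12 (permutation p = 0.290) and -0.653 on the others, where rho over probes with reads in both was -0.0863; a filter on either replicate keeps probes high in a single library, which by construction lowers r. The centre moved from 13.75 Mb to 13.9 Mb with 200 kb and 13.5 Mb with 1 Mb windows. The decay slope was -1.40 from 100 kb, -1.48 with medians, -1.35 without the 10 highest probes and, as added alternatives, -1.08 up to 8 Mb, -1.01 on the lower side, -1.37 on the upper side and -1.31 to -1.30 leaving out a replicate. Windows on other chromosomes numbered 58, with 49 at 1 Mb, 50 at 5 probes, 38 by share of probes, 24 by ranks within chromosomes, 0 at an adjusted p of 0.01, which 10000 draws could not reach in replicate 1, and 77 to 114 in a single replicate. Added alternatives gave 55 with 1000000 draws, 40 with these draws at an adjusted p of 0.01, 19 by probes with at least 10 reads and 0 with 200 kb windows. They gave 0 without chromosomes 6 and 17, where 10000 draws could not call a few windows on their own, and 1 by the negative binomial test. On chromosome 12 the 2 windows became 5 at 1 Mb, 2 beyond 5 Mb, 0 at 200 kb (added), 1 with distance bins of each side alone (added) and 3 to 6 in a single replicate. Gene density had rho 0.103 to 0.133 under the alternatives fixed beforehand; the added limit to windows with a gene turned it to -0.0430, and to -0.0458 without chromosomes 6, 17 and Y. No list passed under the settings fixed beforehand, and 1 did against matched random genes by the mean (added). The difference for probes overlapping a gene kept its direction and its side of the threshold throughout these alternatives. None of them left out assembly gaps or windows without a gene name. Where no cause is stated, the cause was not tested. Planned windows of 200 kb with at least 10 probes and windows of at least 20 probes gave no value, since a 200 kb window holds 4 probes and a 500 kb window 10. No paired analysis was possible because there is 1 group.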

Other observations

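All tests in this part were chosen after the results were seen, and since the design holds 1 group, no biological explanation that needs a comparison of conditions was tested. Away from chromosomes 6, 12 and 17, 15 probes had at least 100 RPM in both replicates, where 3.89 would be shared by chance. They included HPRT1, LDHAL6A (406 and 317 RPM), a relative of the lactate dehydrogenase genes, NRCAM (629 and 170), a neuronal adhesion gene, and GATA6 (137 and 1006), a transcription factor gene. CENPP (679 and 134), RDX (123 and 130) and TPR (1130 and 110), which encode a centromere protein, radixin and a nuclear pore protein, were also among them. These genes were picked by their values, and the 40 probes within 1 Mb of LDHAL6A had reads at 1 and 4 positions.

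The first pattern is the sharp-edged signal on chromosomes 12, 6 and 17. A further equally active copy of the vantage-point fragment on chromosome 6 or 17 would give a window near the top one, whereas the highest reached 1.70% of it in replicate 1 and 0.973% in replicate 2. Extra copies of the chromosome 6 and 17 segments stay open as a candidate explanation. So does a join of their first edges, near PACSIN1 and PPM1E, to chromosome 12 up to KCNJ8. Either would give sharp edges on chromosomes 6 and 17, but extra copies of these segments would not give the edge on chromosome 12. Copies alone would give level detection within a segment and a join a fall from its edge. In 1 Mb blocks of the segment placed from the other library, Spearman's rho of detection with distance from the edge was -0.520 and -0.285 on chromosome 6 (permutation p = 0.0102 and 0.176). On chromosome 17 it was -0.531 and -0.0716 (permutation p = 0.0104 and 0.776). These 2 values cover unlike stretches, 54.1 Mb to 76.35 Mb in replicate 1 and 54.25 Mb to 71.75 Mb in replicate 2. Reads reached 48% and 50% of probes in their first 5 Mb. The 1 Mb window with the highest detection on chromosome 17 lay farther in, from 67 Mb to 68 Mb (80% and 90%). On chromosome 6 it lay from 38 Mb to 39 Mb (95% and 100%). Detection differed between the blocks in both replicates (chi-square p = 0.00849 and 0.00726 on chromosome 6, 1.21e-06 and 4.26e-04 on chromosome 17). It was thus not level, but blocks can also differ in usable HindIII fragments, so this does not decide against copies. Probe by probe in each library's own segment rho was -0.132 and -0.128 on chromosome 6 (Spearman p = 0.00437 and 0.00539). On chromosome 17 it was -0.0222 and -0.149 (Spearman p = 0.678 and 0.00165). These p values treat neighbouring probes as independent, and the same library placed the segment. Within the segments the fall was not shown in both replicates by blocks. On chromosome 6, reads reached 62.25% and 66.25% of probes in the first 20 Mb after the edge, in replicates 1 and 2. In the last 20 Mb of the chromosome they reached 16.75% and 20%. This wider fall was in both replicates, but it runs past the end of the segment. Extra copies that end there would give it too, so it does not separate the 2. Copy number was not measured, and no junction was sequenced.

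The second pattern is the HPRT1 probe. Contact with the X chromosome locus would raise its surroundings, but detection within 1 Mb was 0.188 times that of other chromosomes, and chance amplification of 1 ligation product would not repeat, while the libraries lay within 1.21-fold. A copy of HPRT1 sequence next to the vantage point, for instance within the integrated DNA, and PCR from a primer site at HPRT1 stay open and were not tested. Whether the integrated DNA carries such sequence is not given in the sources used here.

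The third pattern is the shared detection away from chromosomes 6, 12 and 17, at 660 probes (chromosome Y left out) against 232 by chance. Contacts of reproducible strength would give correlated levels, and Spearman's rho over these probes was -0.223. Carry-over, described next, would lower rho whatever the contacts are, and PCR multiplies single ligation events. This value therefore does not decide against such contacts. Reads carried over between the 2 libraries may account for part of it: probes with at least 200 reads in one were detected in the other at least 2.19 times as often as those with fewer reads (1 or more), and 72.0% and 85.4% of those detections had 1 to 3 reads. Carry-over is not the whole cause, since it needs an abundant source: probes with under 10 reads in both libraries were shared 2.76 times as often as chance gives (247 against 89.6). Of probes with a single read in replicate 1 or 2, 17.9% and 20.2% had reads in the other. Of probes with none, 5.95% and 5.58% did. In this last comparison the other library was not limited to few reads, so a single read could itself be carried over. Probes with more usable HindIII fragments would also be shared more often, which was not tested for want of a fragment map and stays open, as does the cause for the 52 probes with at least 10 reads in both, against 27.1 by chance.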
